A study of Mus musculus with 8 samples.

How the data were processed

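The 8 samples were skeletal muscle of female newborn mice of the C57BL/6 strain at postnatal day 2, 4 from mice carrying the ΔDMR1-U2 deletion at the Igf2 locus and 4 from wild-type mice. Per the labels' protocols, RNA was extracted with Trizol and a column cleanup, treated with DNase, depleted of ribosomal RNA and sequenced from both ends on an Illumina HiSeq 2000. Per the submitters' processing notes, the genome build was mm10 and the tools were FastQC 0.10.1, Bowtie2 2.1.0, TopHat2 2.0.9, HTSeq 0.5.4p3 and DESeq2 1.4.5; the settings of these tools, the gene annotation and the strand setting of the counting are not given in the sources used here. The sources used here also do not state from which parent the deletion was inherited, nor the coordinates of the deleted segment. Depletion of ribosomal RNA keeps transcripts without a poly(A) tail, and unspliced precursors can add to the counts of genes.

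One table held the data, with 23336 gene rows. Per the file headers, it gives a raw read count for each gene in each of the 8 samples, as deposited by the authors with no normalization. The same table holds the authors' mean normalised counts over all samples and per group, a signal on the scale of counts divided by size factors, deposited without per-sample values. It further holds the authors' fold change of wild-type over ΔDMR1-U2, a linear ratio, and the authors' log2 of the same ratio. The authors' p-value and adjusted p-value for each gene stand beside them, per the file headers. No count column was left without a sample. Because the authors' ratios run from ΔDMR1-U2 to wild-type, their sign is opposite to the one used here, which is ΔDMR1-U2 over wild-type throughout.

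The raw counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with the filterByExpr function at a minimum count of 10, which left 15241 genes, and 3149 genes had 0 counts in every library. Library sizes were scaled by the trimmed mean of M values, and the groups were compared with the edgeR quasi-likelihood test. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 15241 genes were called higher or lower. Expression levels are given in CPM, the usual rescaling of a count by the scaled library size, and standard errors of log2 fold changes were taken from the fitted test. The table's gene symbols were matched to the GENCODE vM21 annotation of the same mouse assembly, directly for most genes and through an older symbol for 1890, and 303 of 23336 symbols were not matched. Igf2as is the older symbol of the gene that the annotation lists as Igf2os.

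Each gene group was a list of symbols fixed before the data were examined, as were the tests, the thresholds and the alternatives, except for those said to be added later. Of 33 lists, 31 had at least 5 tested members. They covered the Igf2 locus, imprinted genes, growth factor signalling, muscle fibre types, fuel use, cell division, stress and hormone responses, and markers of other cell types a dissection could hold. The list of mitochondrially encoded genes had 0 members in the table, and the list of Y-linked genes had 0 members past the filter. Lists were tested against all other genes with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 31 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were run as alternatives. For each list tested, the count of members with an adjusted p under 0.05 adjusted over the list alone is also given.

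The genes named in the text follow a rule set in advance. It takes every detected gene of the Igf2 locus list, the 15 called genes with the smallest p in each direction, and for each list up to 4 called members with the largest change or, where none was called, the 2 most abundant members. Some genes that this rule takes are not reported here. Any other gene named was chosen after its values were seen, as were the examples given for members past the threshold adjusted over the list alone.

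Total counts per library ran from 16084413 to 26913636. The biological coefficient of variation was 12.3%. On simulated counts for 15082 genes drawn from the means and library sizes of this comparison, the test recovered 61.2% of genes changed 1.5-fold, 88.0% of genes changed 2-fold and 100.0% of genes changed 3-fold or 4-fold, and 10 of the 186 genes called were unchanged ones. The simulated changed list, fatty acid oxidation, was called, with 0 of the unchanged lists, not counting the muscle atrophy, glucocorticoid, white adipocyte and brown adipocyte lists. The glucocorticoid list shares Angptl4 and the brown adipocyte list Cpt1b with the changed list. The muscle atrophy and white adipocyte lists share no gene with it, so the 0 does not cover all unchanged lists. Genes were simulated independently of each other, so this does not test list calls where genes move together. In the real data the estimated correlation between genes was 0.46 for the fatty acid oxidation list. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 11.1 to 24.5, so none was a second copy of another, and each was counted as 1 replicate by its label. This does not show that each came from a separate animal, which is not given in the sources used here, although ΔDMR1-U2 libraries 1A and 1B differed in Xist as 1 animal would not. Where libraries share an animal, the p values measure only the spread between samples, which may be technical.

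Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with and without sample weights, other filters and thresholds, a test against a fold of 1.2, library sizes without the 10 most abundant genes, the authors' deposited statistics, the replicate number of the titles as a block, and each library left out in turn. After the data were seen, 3 alternatives were added, namely both ΔDMR1-U2 libraries 1A and 1B left out together, 1 surrogate variable estimated with sva 3.50.0, and X-linked genes left out. Figures were drawn with matplotlib 3.10.9.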

Results

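Gene expression was measured by total RNA sequencing in 4 ΔDMR1-U2 and 4 wild-type samples of skeletal muscle from female mice at postnatal day 2. ΔDMR1-U2 mice carry a deletion at Igf2, the imprinted gene for insulin-like growth factor 2, that is named for a differentially methylated region (DMR1), and the study is about transcripts of Igf2as, the gene that runs antisense to Igf2. The libraries held 16781493 to 20060129 counts in ΔDMR1-U2 and 16084413 to 26913636 in wild-type. Titin (Ttn) took 11.3% ± 0.662 of all counts in ΔDMR1-U2 and 12.1% ± 0.504 in wild-type. The first principal component held 38.0% of the variance, and ΔDMR1-U2 library 1B lay at its end, at a score of -41.7 against -16.9 to 23.9 in the other 7 libraries. ΔDMR1-U2 library 1A had 49 counts of Xist, the RNA of the inactive X chromosome, or 2.50 CPM, against 1270 to 1895 CPM in the other 7 libraries. Both libraries carried the low Igf2as level of their group.

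The first question was what the deletion does to the genes of its own locus. Igf2as was 10.7-fold lower in ΔDMR1-U2 muscle, at 5.93 ± 0.269 CPM against 63.5 ± 9.70 CPM in wild-type (SD, n = 4 each). Igf2, on the opposite strand, was at 5128 ± 381 CPM in ΔDMR1-U2 and 4948 ± 289 CPM in wild-type, a difference smaller than the spread between libraries. H19, the untranslated RNA of the same imprinted domain, was at 17929 ± 1169 CPM against 16768 ± 1492 CPM. Th, which encodes tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, was 3.79-fold higher, from 0.475 ± 0.20 to 1.79 ± 0.294 CPM.

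Igf2as had 121, 104, 100 and 122 counts in ΔDMR1-U2 libraries 1A, 1B, 2 and 3, and 1113, 1868, 1490 and 1282 counts in the wild-type libraries of the same names. Its log2 fold change was -3.42 with a standard error of 0.12 (adjusted p = 1.82e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and the authors' deposited table gives a wild-type to ΔDMR1-U2 fold of 10.7. In the mm10 build, Igf2as lies on chromosome 7 from 142659693 to 142670356 on the plus strand, and Igf2 lies on the minus strand from 142650766 to 142666816. The annotation places the last Igf2as exon, from 142667186 to 142670356, beyond the annotated Igf2 gene, while its other exons overlap Igf2. Because the strand setting of the counting is not given in the sources used here, reads from the overlapping part of the 2 genes cannot be told apart. The position of the deleted segment relative to the counted exons is likewise not given, so the low count does not separate missing sequence from missing transcription. Igf2 had a log2 fold change of 0.05 with a standard error of 0.08 (adjusted p = 0.761, edgeR), and H19, at 142575529 to 142578143, one of 0.10 with a standard error of 0.09 (adjusted p = 0.587, edgeR).

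**Figure D1:**
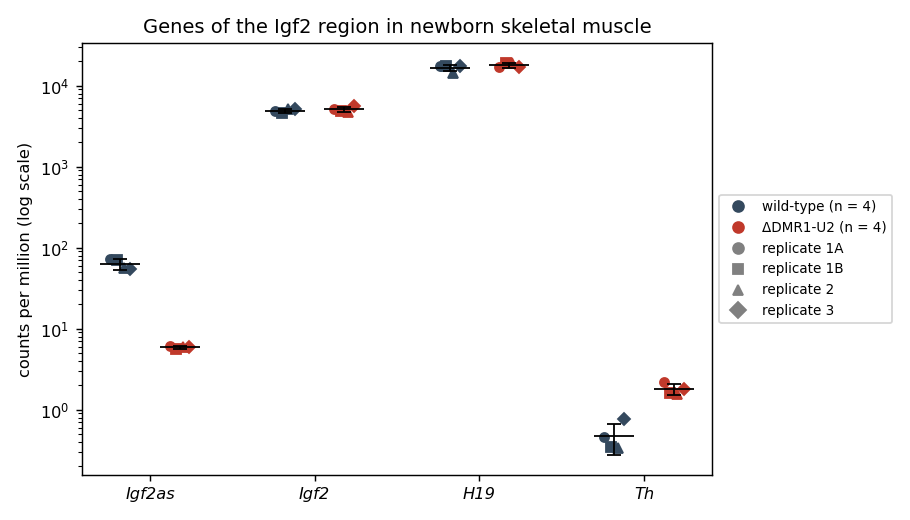
Expression in CPM (log axis) of Igf2as, Igf2, H19 and Th in each of the 4 wild-type and 4 ΔDMR1-U2 libraries, with horizontal bars for the group mean and error bars for 1 SD. Igf2as sits between 5.55 and 6.18 CPM in the ΔDMR1-U2 libraries and between 54.4 and 72.2 CPM in the wild-type libraries, while the groups overlap for Igf2 and H19.

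Of 16 tested genes of the Igf2 locus and the adjoining imprinted cluster, 1 rose and 1 fell over all genes tested, Th and Igf2as. Th, on chromosome 7 from 142892752 to 142931128, had a log2 fold change of 1.92 with a standard error of 0.28 (adjusted p = 0.0231, edgeR), resting on 26 to 43 counts per ΔDMR1-U2 library and 7 to 18 per wild-type library. Its call was lost without ΔDMR1-U2 library 3 or wild-type library 1A, 1B or 2, while its log2 fold change stayed between 1.77 and 2.27 in the 8 fits that each left out 1 library. The imprinted genes Kcnq1ot1 and Cdkn1c, a cell cycle inhibitor, had log2 fold changes of 0.21 and -0.17, and Kcnq1 had -0.22. That of Cdkn1c ran from -0.22 to -0.02 when 1 library was left out. The muscle troponin genes of this region, Tnnt3 and Tnni2, had -0.15 and -0.21. Tspan32 had 0.45, Cd81 had -0.08, Tssc4 had -0.17, Nap1l4 had -0.15, Mrpl23 had 0.14 and Ctsd had 0.20, and none of these genes was called by edgeR. Lsp1 had 0.30 and passed in edgeR when adjusted over the list alone (adjusted p = 0.0332, edgeR), where the list counts 2 higher and 1 lower, and in DESeq2 over all genes (adjusted p = 0.0497). The list was not called by camera (adjusted p = 0.907). Ascl2, Slc22a18, Phlda2 and Syt8 stayed below the filter on low counts. Kcnq1 and Kcnq1ot1 overlap on opposite strands, with the same limit as Igf2as and Igf2.

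Across the transcriptome, 172 of 15241 tested genes differed between ΔDMR1-U2 and wild-type muscle, 78 of them higher and 94 lower in ΔDMR1-U2. The changes were moderate, with a median absolute log2 fold change of 0.66 and 39 genes changed at least 2-fold, 21 higher and 18 lower. Genes of fatty acid uptake and use, Angptl4, Cd36 and Acot2, were among those higher. Genes of glycogen and sugar handling, Gys1, Slc37a4 and Slc2a5, were among those lower. The groups did not overlap in 171 of the 172 called genes, the exception being Myl9, and in 12.8% of all tested genes, where chance gives 2.86%. Unadjusted, 3243 of the 15241 genes had a p under 0.05, where chance gives 762. The unadjusted counts given below for gene lists are to be read against this share of all genes.

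The count depended on single libraries. It was 137 without ΔDMR1-U2 library 1A, 116 without 1B, of which 49 were higher, and 16 without both. It was 631 without ΔDMR1-U2 library 2, 7 without 3, and 7, 20, 10 and 22 without wild-type libraries 1A, 1B, 2 and 3. In each of these 8 fits that left out 1 library, 6 genes were called, namely Igf2as, Cd36, Angptl4, Mrgprb1, Calcrl and Got1. The authors' deposited table holds 179 genes under the same threshold, 56 higher and 123 lower in ΔDMR1-U2, of which 111 were among the 172.

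Among the genes with the smallest p, Calcrl, the receptor component for calcitonin gene-related peptide and adrenomedullin, rose from 94.4 ± 3.20 to 144 ± 8.47 CPM, a log2 fold change of 0.61 with a standard error of 0.06 (adjusted p = 0.00532, edgeR). Mrgprb1, a Mas-related receptor of a multigene family whose members can share reads, rose by 0.95 on the log2 scale with a standard error of 0.11 (adjusted p = 0.00752, edgeR). Apart from Th, described above, the other genes of this kind outside fuel use were Emp2, Stom, Klf11, 2310046A06Rik, Fgl2, Col23a1, Plag1, Kcna2 and Plscr4, with log2 fold changes of 0.48 for Col23a1, a collagen, to 0.97 for Kcna2, a voltage-gated potassium channel. Klf11 and Plag1, both zinc-finger transcription factors, each rose by 0.53. The genes lower in ΔDMR1-U2 included Camk2b, the beta chain of a calcium-dependent kinase, at -0.93, Esr1, the oestrogen receptor, at -0.82, Rps6ka2, a ribosomal S6 kinase, at -0.63, and Lynx1, a modulator of acetylcholine receptors, at -0.56. Fam19a3, a secreted peptide, fell by 1.45 on the log2 scale, 1700113I22Rik by 0.76, Trim7, a partner of glycogenin, by 0.63, and Glrx5, a protein of iron-sulphur cluster assembly, by 0.53. Fgl2, Fam19a3 and 1700113I22Rik overlap other genes on the opposite strand. Apart from Calcrl and Mrgprb1, the genes named here lost their calls without ΔDMR1-U2 library 3 and without wild-type library 1A, and most without a further wild-type library, with highest adjusted p values of 0.0575 to 0.108 in these fits (edgeR). The direction of each was kept.

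Fatty acid genes were higher in ΔDMR1-U2 muscle. Of 29 tested genes of fatty acid uptake and oxidation, 5 rose and 24 were not called, and 15 rose when adjusted over the list alone. Acot2, a mitochondrial acyl-CoA thioesterase, rose by 1.44 on the log2 scale with a standard error of 0.24, from 31.0 ± 3.56 to 83.9 ± 35.6 CPM. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 1.19 with a standard error of 0.12, from 40.5 ± 5.12 to 92.4 ± 15.8 CPM, and Cd36, the fatty acid transporter, rose by 0.80 with a standard error of 0.09, from 409 ± 21.8 to 711 ± 85.6 CPM.

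The adjusted p values were 0.0301 for Acot2, 0.00532 for Angptl4 and 0.00752 for Cd36 (edgeR quasi-likelihood test, Benjamini-Hochberg). Angptl4 lies on chromosome 17 from 33773750 to 33781830 and Cd36 on chromosome 5 from 17781690 to 17888801. The called member with the smallest change was Mlycd, malonyl-CoA decarboxylase, at 0.49, which kept its call only without ΔDMR1-U2 library 1A or 2. Acot2 is a close paralog of Acot1, which was also called at 1.68, and the counting could split reads between them. Among members past the threshold adjusted over the list alone, Ppara, the lipid-sensing nuclear receptor, had 1.00, Plin5, a lipid droplet protein, 1.19, Cpt1b 0.54 and Lpl, lipoprotein lipase, 0.48. Without ΔDMR1-U2 library 1B, Ppara was at 0.37 and Plin5 at 0.58. The list had a median log2 fold change of 0.33 and was called higher by camera (adjusted p = 6.38e-09), with adjusted p = 0.686 with an estimated correlation. White adipocyte markers had a median log2 fold change of 0.37, and this rested on ΔDMR1-U2 library 1B, which lay 1.24 above the wild-type mean against -0.40 to 0.22 in the other libraries. Without library 1B the adipocyte median was -0.12 and that of the fatty acid oxidation list 0.23. Acot2 lost its call without ΔDMR1-U2 library 3 or any single wild-type library, with log2 fold changes of 1.12 to 1.60.

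**Figure D2:**
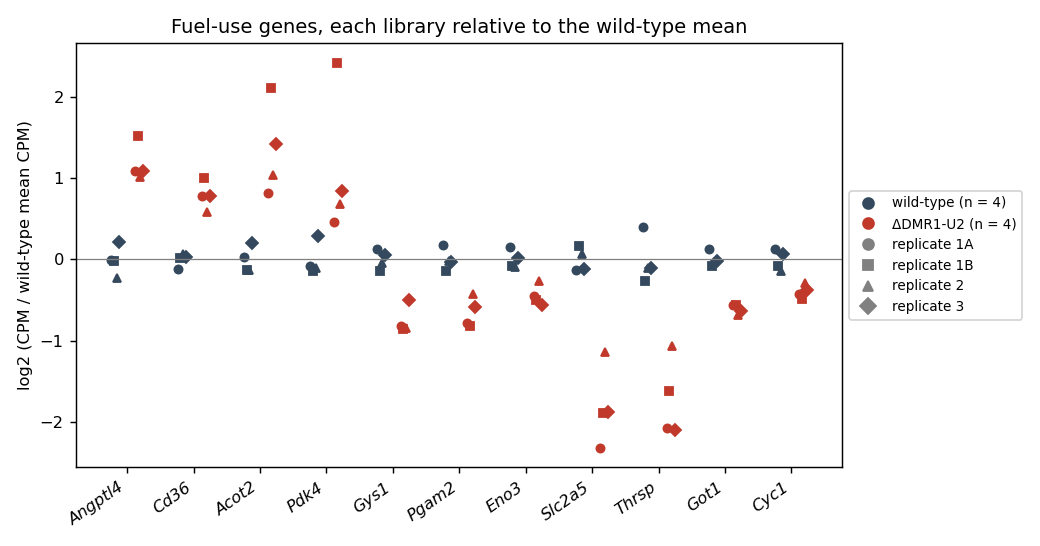
Log2 of each library's CPM over the wild-type mean CPM for 11 genes of fuel use, with wild-type libraries in grey-blue and ΔDMR1-U2 libraries in red and a marker shape per replicate name. Angptl4, Cd36 and Acot2 lie above the wild-type libraries in all 4 ΔDMR1-U2 libraries, Gys1, Pgam2, Eno3, Slc2a5, Thrsp, Got1 and Cyc1 lie below them, and Pdk4 is at 647 CPM in ΔDMR1-U2 library 1B against 165 to 216 CPM in the other 3 of its group.

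Genes of glucose use were lower. Of 25 tested genes of glycolysis and glycogen, 3 fell and 22 were not called, and 8 fell when adjusted over the list alone. Gys1, muscle glycogen synthase, fell by 0.75 on the log2 scale with a standard error of 0.09, from 129 ± 10.7 to 77.0 ± 9.43 CPM. Pgam2, the muscle phosphoglycerate mutase, fell by 0.64 with a standard error of 0.10, from 460 ± 43.5 to 295 ± 38.7 CPM, and Eno3, muscle enolase, fell by 0.44 with a standard error of 0.09, from 2122 ± 174 to 1566 ± 142 CPM.

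The adjusted p values were 0.0110 for Gys1, 0.0301 for Pgam2 and 0.0475 for Eno3 (edgeR quasi-likelihood test, Benjamini-Hochberg), and Gys1, on chromosome 7 from 45434844 to 45456619, overlaps Ruvbl2 on the opposite strand. Outside the list, Slc37a4, the glucose-6-phosphate transporter, fell by 0.80 on the log2 scale, and Slc2a5, the fructose transporter, fell by 1.76 with a standard error of 0.22, from 4.34 ± 0.442 to 1.30 ± 0.470 CPM. Thrsp, a regulator of fatty acid synthesis, fell by 1.66 with a standard error of 0.22, and Got1, the cytosolic aspartate aminotransferase, fell by 0.61 with a standard error of 0.07 (adjusted p = 0.0156 for Thrsp and 0.00752 for Got1, edgeR). The glycolysis list had a median log2 fold change of -0.17 and was called lower by camera (adjusted p = 1.70e-05), with adjusted p = 0.686 with an estimated correlation. The call of Gys1 was lost without wild-type library 1A. Slc37a4 lost its call without ΔDMR1-U2 library 3 or wild-type library 1A, Slc2a5 without ΔDMR1-U2 library 3 or wild-type library 2, and Thrsp without any 1 of ΔDMR1-U2 library 3 and wild-type libraries 1A and 2. Pgam2 lost its call without ΔDMR1-U2 library 3 or any single wild-type library, and Eno3 without any single library other than ΔDMR1-U2 library 2.

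Fast fibre genes and genes of mitochondrial respiration were also lower. Of 20 tested fast muscle fibre genes, 3 fell, Pgam2, Eno3 and Tnnc2, the fast troponin C, and 9 fell when adjusted over the list alone, among them Casq1 at -0.58, Mylpf at -0.33 and Myh4 at -0.30. Tnnc2 fell by 0.39 on the log2 scale with a standard error of 0.07, from 3257 ± 137 to 2492 ± 82.7 CPM (adjusted p = 0.0348, edgeR). Of 40 tested genes of oxidative phosphorylation, 2 fell, Cyc1, cytochrome c1, and Atp5g1, a subunit of ATP synthase, both by 0.39 on the log2 scale, and 10 fell when adjusted over the list alone. The changes of the whole lists were small, with median log2 fold changes of -0.25 for the fast fibre list and -0.19 for oxidative phosphorylation. In the latter 38 of 40 genes had a negative value, but these genes move together, with an estimated correlation of 0.52. Its medians per library overlapped, at -0.08 in ΔDMR1-U2 library 2 and -0.14 in wild-type library 2.

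Both lists were called lower by camera (adjusted p = 4.01e-07 for fast fibre genes and 1.26e-10 for oxidative phosphorylation), each with adjusted p = 0.686 with an estimated correlation. The fast fibre list shares Pgam2, Eno3 and Pfkm with the glycolysis list. Atp5g1 belongs to a family of near-identical subunit genes. Tnnc2 overlaps Ube2c on the opposite strand. Cyc1 and Atp5g1 lost their calls without any single library other than ΔDMR1-U2 library 2, and Tnnc2 without any other than ΔDMR1-U2 libraries 1A and 2. Of 17 slow fibre genes, 1 rose and 1 fell. Mb, myoglobin, which overlaps Apol6 on the opposite strand, fell by 0.78 on the log2 scale, and Sln, sarcolipin, a regulator of the calcium pump, rose by 0.66 (adjusted p = 0.0348 and 0.0411, edgeR). The slow fibre list was not called (median log2 fold change -0.04, camera adjusted p = 0.600). Among 29 myogenic regulators, Fst, follistatin, rose by 0.53 and 28 were not called (median -0.10, camera adjusted p = 0.139), though the list was called lower without wild-type library 3 and with no filter on low counts. The myogenic median was -0.03 without wild-type library 1A and -0.04 without ΔDMR1-U2 library 1B, and the slow fibre median ran from -0.10 to 0.05 when 1 library was left out. Mb and Sln kept their calls only in the fits without ΔDMR1-U2 library 1A or 2, and Fst only in the fit without ΔDMR1-U2 library 2.

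Genes of growth factor signalling moved in both directions. Of 30 tested genes, Igf2bp2, an mRNA-binding protein named for its binding to Igf2 mRNA, rose by 0.36 on the log2 scale with a standard error of 0.07 (adjusted p = 0.0370, edgeR), and Igfbp7, a secreted binding protein, fell by 0.49 with a standard error of 0.09 (adjusted p = 0.0392, edgeR). Adjusted over the list alone, 8 rose and 5 fell. Those higher included Pappa and Pappa2, proteases that cleave growth factor binding proteins, at 1.36 and 0.77, Igf1r, the main receptor of the pathway, at 0.45, Insr, the insulin receptor, at 0.34 and Irs2 at 0.62, the last 2 at 0.22 and 0.37 without ΔDMR1-U2 library 1B. Those lower included Igfbp2 at -0.57 and Grb14, an inhibitor of insulin receptor signalling, at -0.47. None of these members was called over all genes in the main comparison. In the 8 fits that left out 1 library, Pappa was called in 2, Igf1r and Igfbp2 in 1 each, and Pappa2, Insr, Irs2 and Grb14 in 0. The list was not called (median log2 fold change 0.07, 0.04 to 0.11 when 1 library was left out, camera adjusted p = 0.245). Igfbp7 overlaps Polr2b on the opposite strand. Igf2bp2 kept its call only without ΔDMR1-U2 library 1A or 2, and Igfbp7 only without ΔDMR1-U2 library 1B or 2. Of 36 imprinted genes elsewhere in the genome, Zim1 rose by 0.47 (adjusted p = 0.0344, edgeR), from 453 ± 5.77 to 629 ± 72.9 CPM, and 35 were not called. Adjusted over the list alone, 2 rose, Zim1 and its neighbour Usp29, and 1 fell, Peg12. That list was not called (median 0.02, -0.00 to 0.04 when 1 library was left out, camera adjusted p = 0.341), and Zim1 lost its call without ΔDMR1-U2 library 3 or any single wild-type library.

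Genes of cell division and sterol synthesis were lower as groups, with 0 members called by edgeR or limma-voom. All 36 tested genes of the cell cycle list had negative log2 fold changes, with a median of -0.29, and 1 fell when adjusted over the list alone, Ccne1, cyclin E1, at -0.82. Of these genes, 20 were lower at an unadjusted p under 0.05, and DESeq2 called 3 lower. Mki67 and Top2a, the most abundant members, had -0.23 and -0.32. Cholesterol synthesis genes had a median of -0.24 over 24 genes, with Hmgcs1 at -0.18 and Srebf2 at -0.26, and 2 fell when adjusted over the list alone, among them Fdps at -0.46, while 7 were lower at an unadjusted p under 0.05 and DESeq2 called 2 lower. Camera called both lists lower (adjusted p = 1.46e-09 and 0.000390), each with adjusted p = 0.686 with an estimated correlation. The cell cycle medians per library, relative to the wild-type mean, were -0.44 and -0.37 in ΔDMR1-U2 libraries 3 and 1B and -0.15 and -0.05 in 1A and 2, and that of wild-type library 3 was -0.23, so the groups overlapped. Without ΔDMR1-U2 library 1B the cholesterol median was -0.16, and the cholesterol call was lost with 1 surrogate variable.

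Glucocorticoid-responsive, muscle atrophy and immediate early genes were higher to an extent set by ΔDMR1-U2 library 1B. Glucocorticoid-responsive genes had a median log2 fold change of 1.05, with all 16 above 0, 1 called, Angptl4, and 10 higher when adjusted over the list alone, among them Fkbp5 at 1.49, Zbtb16 at 1.62 and Pdk4, a brake on pyruvate use, at 1.34. Without library 1B, Fkbp5 was at 0.42, Zbtb16 at 0.64 and Pdk4 at 0.67, where Pdk4 was called (adjusted p = 0.0334, edgeR). Library 1B lay 1.81 above the wild-type mean on this list and the other 3 ΔDMR1-U2 libraries 0.28 to 0.61 above it. Without library 1B the median was 0.40, and 2 members were called higher. Muscle atrophy and autophagy genes had a median of 0.26 over 28 genes with 0 called by edgeR or limma-voom over all genes, 1 by DESeq2, 10 higher at an unadjusted p under 0.05 and 1 higher adjusted over the list alone, Bnip3 at 1.00. Without library 1B this median was 0.08, and 2 members were called higher, Bnip3 at 0.62 among them (adjusted p = 0.0180, edgeR). Nedd4, the most abundant of this list, had 0.05. Immediate early and heat shock genes had a median of 0.24, and without library 1B it was 0.07. Hspb1 had 0.28, or 0.07 to 0.48 when 1 library was left out, and Hsp90aa1 had -0.02. Of the 24 genes of this list 0 were called by edgeR, limma-voom or DESeq2. At an unadjusted p under 0.05, 3 were higher and 0 lower, a smaller share than the 3243 of 15241 over all genes. Camera called the 3 lists higher (adjusted p = 3.99e-06, 0.000238 and 0.0228), with adjusted p = 0.686, 0.758 and 0.686 with an estimated correlation, and all 3 calls were lost with 1 surrogate variable. The immediate early call was also lost without ΔDMR1-U2 library 1B or 2 or wild-type library 2, and at an adjusted p under 0.01. Its median was 0.15 without wild-type library 2 and 0.16 without wild-type library 3. Library 1B was also the highest for epidermis markers, at 1.27 above the wild-type mean against -0.17 to 0.20 in the other libraries.

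Markers of neutrophils and of nerve were higher in ΔDMR1-U2, while the other lists of blood cells were not called. Neutrophil and bone marrow genes had a median log2 fold change of 1.03 over 10 genes, with S100a9 at 1.04 and S100a8 at 0.94, 0 called by edgeR or limma-voom over all genes, 1 by DESeq2, 7 higher at an unadjusted p under 0.05 and 5 higher when adjusted over the list alone, among them Lcn2 at 2.97, or 1.96 without ΔDMR1-U2 library 1B, and Mpo at 1.03. Their medians per library ran from 0.70 to 1.85 above the wild-type mean in ΔDMR1-U2 and from -1.04 to 1.12 in wild-type, so the groups overlapped. Without ΔDMR1-U2 libraries 1A and 1B the median log2 fold change was 0.62. Lcn2 is also a member of the glucocorticoid list, and was at 62.7 CPM in ΔDMR1-U2 library 1B against 6.09 to 20.3 CPM in the others of its group. Schwann cell and nerve genes had a median of 0.29 over 17 genes, with Pmp22 at 0.13, and 1 higher adjusted over the list alone. Of these, 0 were called by edgeR or limma-voom, 2 by DESeq2, and 5 were higher at an unadjusted p under 0.05. Without ΔDMR1-U2 library 1A this median was 0.15, and the call was lost without wild-type library 3. Camera called both lists higher (adjusted p = 0.000156 and 0.00756), each with adjusted p = 0.686 with an estimated correlation.

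Interferon-stimulated genes were lower, with a median log2 fold change of -0.36 over 25 genes, 24 of them negative. Bst2, tetherin, fell by 0.62 on the log2 scale with a standard error of 0.12 (adjusted p = 0.0379, edgeR), the single called member, and kept its call only in the fit without ΔDMR1-U2 library 2. Camera called the list lower (adjusted p = 7.33e-05), with adjusted p = 0.710 with an estimated correlation. The median was -0.19 without wild-type library 2. The groups overlapped, with medians per library of -0.68 to -0.12 in ΔDMR1-U2 and, in wild-type, of -0.40 in library 1A to 0.31 in library 2. Tendon markers had a median of -0.45 over 11 genes with 0 called by edgeR, limma-voom or DESeq2 and 0 at an unadjusted p under 0.05, Col11a1 at -0.45 and Thbs4 at -0.28, and camera called the list lower (adjusted p = 0.0314), with adjusted p = 0.794 with an estimated correlation. The median of ΔDMR1-U2 library 3 relative to the wild-type mean was -1.45 on this list. The call was lost without ΔDMR1-U2 library 3 or wild-type library 1B, 2 or 3, with X-linked genes left out, with 1 surrogate variable and at an adjusted p under 0.01. The tendon median was -0.15 without ΔDMR1-U2 library 3, -0.68 without ΔDMR1-U2 library 2, -0.29 without wild-type library 1B and -0.27 without wild-type library 3. When 1 library was left out, Col11a1 ran from -0.68 to -0.17 and Thbs4 from -0.38 to -0.14.

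**Figure D3:**
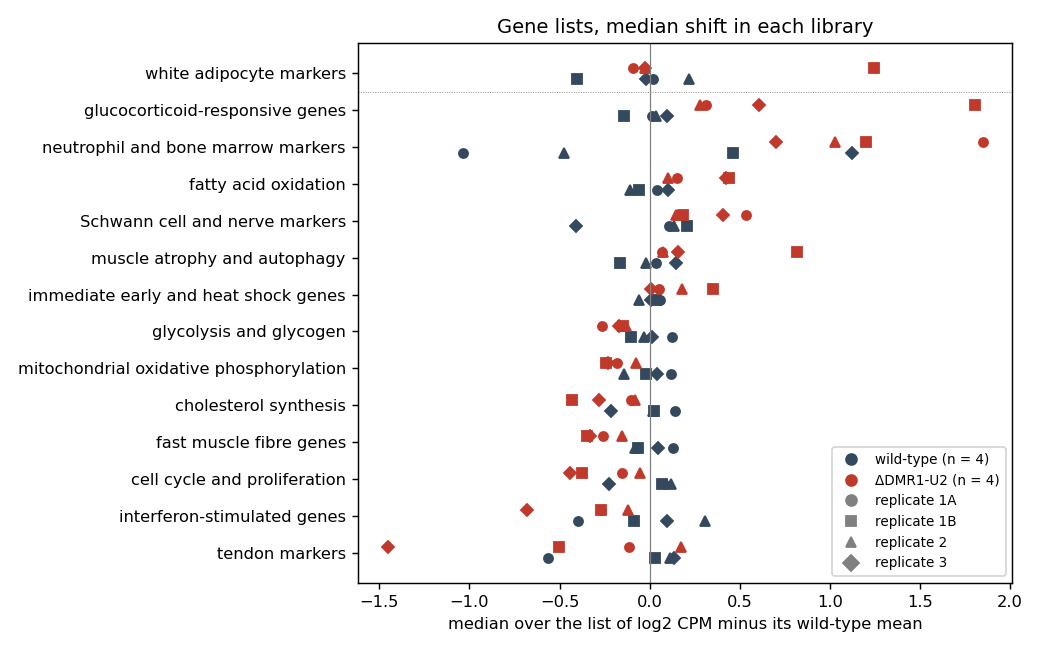
Median over each gene list of log2 CPM minus the gene's wild-type mean, 1 point per library, for the 13 lists called by camera and, above the dotted line, white adipocyte markers. ΔDMR1-U2 library 1B (red square) lies at 1.81 for glucocorticoid-responsive genes and at 1.24 for white adipocyte markers, apart from the other libraries.

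Of the 13 called lists, the fast fibre, glycolysis and glucocorticoid lists had medians per library that separated the groups, and in the other 10 the groups overlapped. Called lists that share members are not independent results. Besides the fast fibre and glycolysis lists, the glucocorticoid list shares Pdk4, Klf15, Mt1, Mt2 and Ddit4 with muscle atrophy. It also shares Lcn2 with the neutrophil list and Angptl4 with fatty acid oxidation. The immediate early list shares Egr1 with tendon and Egr2 with nerve markers. The remaining lists were not called by camera in the main comparison. Among vessel genes, Apln, the ligand apelin, fell by 1.71 on the log2 scale with a standard error of 0.32, from 39.0 ± 4.19 to 12 ± 6.81 CPM (adjusted p = 0.0370, edgeR), while 17 of 18 endothelial genes were not called and their median was 0.04, or 0.01 to 0.10 when 1 library was left out. Cidea, a lipid droplet protein abundant in brown fat, rose by 1.07 (adjusted p = 0.0301, edgeR), while the other 11 brown adipocyte genes were not called and the list's median was 0.02, or -0.02 to 0.07 when 1 library was left out. Asns, asparagine synthetase, fell by 0.74 (adjusted p = 0.0475, edgeR), and the median of its stress response list was -0.00100. That list was called lower without ΔDMR1-U2 library 1B, where its median was -0.16 (camera adjusted p = 0.00205), without both libraries 1A and 1B and with 1 surrogate variable. Apln kept its call only without ΔDMR1-U2 library 1B or 2, Cidea only without ΔDMR1-U2 library 1A, 1B or 2, and Asns only without ΔDMR1-U2 library 1B or 2 or wild-type library 3. No member was called by edgeR over all genes in the lists of extracellular matrix (median -0.08), cartilage and bone (-0.25), white adipocyte (0.37), smooth muscle (-0.02), erythroid (0.04), macrophage (-0.06), lymphocyte and mast cell (0.16), epidermis (0.50), circadian clock (0.10) and nuclear RNA genes (-0.07). In each of these lists limma-voom called 0 members and DESeq2 0 to 3, and 1 to 8 members had an unadjusted p under 0.05. Adjusted over the list alone, 4 rose and 1 fell among white adipocyte genes, 3 rose and 1 fell among erythroid and 1 rose and 1 fell among slow fibre genes, 1 rose among myogenic regulators and 1 among brown adipocyte genes, 2 endothelial genes fell, 1 fell in each of the extracellular matrix, smooth muscle, circadian clock, nuclear RNA, interferon and stress response lists, and 0 passed in the tendon, cartilage and bone, macrophage, lymphocyte and mast cell, epidermis and immediate early lists. Several of these medians rested on single libraries. Leaving out 1 library gave -0.70 to 0.27 for cartilage and bone, above 0 only without wild-type library 3, -0.09 to 0.37 for erythroid, highest without wild-type library 3, and 0.09 to 0.66 for epidermis, lowest without ΔDMR1-U2 library 1B. It gave -0.12 to 0.53 for white adipocyte, below 0 only without library 1B, -0.18 to 0.00 for macrophage, 0.07 to 0.25 for lymphocyte and mast cell, -0.06 to 0.05 for smooth muscle, -0.12 to -0.02 for extracellular matrix, 0.06 to 0.13 for circadian clock and -0.14 to 0.06 for nuclear RNA genes. Camera called cartilage and bone and extracellular matrix lower without wild-type library 1A and epidermis higher without ΔDMR1-U2 library 1A, with the replicate number as 4 blocks and with no filter on low counts. With 1 surrogate variable the extracellular matrix, macrophage and white adipocyte lists were called lower, the extracellular matrix and macrophage lists also without both libraries 1A and 1B. Of their most abundant members, Tfrc, the transferrin receptor, had -0.57 and was called lower by DESeq2 (adjusted p = 0.000990), by edgeR with no filter on low counts (adjusted p = 0.0370) and in the authors' deposited table (adjusted p = 0.0199). Plin4, a lipid droplet protein, had 1.17, with 652 CPM in ΔDMR1-U2 library 1B against 214 to 292 CPM in the other 3 of its group, was at 0.66 without library 1B and was called without ΔDMR1-U2 library 2 (adjusted p = 0.0469, edgeR), and Col2a1, the cartilage collagen, had -0.87 with a standard error of 0.94; edgeR called none of the 3 genes in the main comparison. Col3a1, Col1a2, Car3, Des, Abcc9, Alas2, Mrc1, Csf1r, Cpa3, Cma1, Trp63, Krt10, Spp1, Clock, Tef, Malat1 and Rn45s had values between -0.30 for Col1a2 and 0.23 for Cpa3, and those of Alas2, Car3, Col3a1, Des, Krt10, Spp1, Tef and Trp63 changed sign when single libraries were left out.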

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

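The tests for fat tissue and for library 1B given here were chosen after the result was seen; the test of fatty acid synthesis genes was set before its values were seen. Among 194 groups of 4 libraries, one per genotype for each of the 94 genes taken by the naming rule, Xist, the total counts and the Ttn share, 15 had a library set apart from the other 3 by more than 0.829 of the group's range, where chance would give 9.7.

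Angptl4 reached 115.9 CPM in ΔDMR1-U2 library 1B against 81.8 to 86.3 CPM in the other 3 of its group, and Pdk4 reached 646.6 CPM there against 165 to 216 CPM. Angptl4 and Pdk4 belong to the glucocorticoid list, whose median in library 1B was 1.81, against 0.28 to 0.61 in the other 3. Fkbp5, of the same list, was at 141 CPM in library 1B against 24.8 to 28.8 CPM. The cause of the rise of that list was not tested. The set of fatty acid oxidation genes was higher in ΔDMR1-U2, with a median log2 fold change of 0.33. Fat in the dissection of that library is a candidate explanation for part of it, since 9 genes restricted to adipocytes, Adipoq and Plin1 among them, had a median of 0.4563 with all libraries. Without library 1B their median was -0.1683 (bootstrap interval -0.33 to 0.14) while that of the oxidation genes was 0.2261 (0.17 to 0.35). These medians argue against fat or library 1B as the whole cause of the higher median. The bootstrap intervals in this paragraph resample genes, which move together, so they do not measure the spread between libraries. The oxidation medians per library were 0.15, 0.10 and 0.42 in ΔDMR1-U2 libraries 1A, 2 and 3. The highest in wild-type was 0.10 in library 3, just above that of ΔDMR1-U2 library 2. The most abundant of the 9, Lipe, Cfd and Adipoq, had 31.2, 23.4 and 18.4 CPM in ΔDMR1-U2, and muscle itself also expresses Lipe. Lower nutrient supply to the ΔDMR1-U2 pups and an effect of the genotype itself stay open, since 14 genes of fatty acid synthesis had a median of -0.1331, short of the -0.30 set in advance, with an interval of -0.25 to 0.02 that reaches above 0.

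Other libraries set apart from their group were the following, as values in CPM. Among genes of the Igf2 region, H19 was at 14530 in wild-type library 2 against 17430 to 17570, Cdkn1c was at 1160 in wild-type library 1A against 792 to 833, Nap1l4 was at 116.0 in ΔDMR1-U2 library 1B against 137 to 140, and Tnnt3 was at 3698 in ΔDMR1-U2 library 3 against 3910 to 3918. Among called genes, Stom was at 47.27 in wild-type library 2 against 42.8 to 43.2, Klf11 at 65.84 in ΔDMR1-U2 library 1A against 52.5 to 54.7, Gys1 at 91.06 in ΔDMR1-U2 library 3 against 71.3 to 73.3, Tnnc2 at 2615 in ΔDMR1-U2 library 1A against 2440 to 2464, and Bst2 at 15.89 in wild-type library 2 against 14.0 to 14.2. Pdk4 was at 147.1 in wild-type library 3 against 109 to 114, Col11a1 at 192.3 in wild-type library 1A against 444 to 477, Alas2 at 71.43 in wild-type library 3 against 29.8 to 30.8, and Krt10 at 9.123 in ΔDMR1-U2 library 1B against 5.36 to 5.87.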

How the results depend on the processing

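The settings without both libraries 1A and 1B, with 1 surrogate variable and without X-linked genes were chosen after the data were seen. Igf2as kept its call and its direction, and Igf2 stayed uncalled with a value above 0, under all alternatives run, with log2 fold changes of -3.49 to -3.26 for Igf2as. Genes called were 172 (78 higher, 94 lower) in the main comparison. They were 962 (459 and 503) with DESeq2, 814 (390 and 424) at an adjusted p under 0.10, 6 (4 and 2) at 0.01, and 7 (4 and 3) when tested against a fold of 1.2; the last 3 follow from the threshold, and the cause of the first was not tested. Leaving out 1 library gave 7 to 631 genes, 4 to 294 higher and 3 to 337 lower. Leaving out both ΔDMR1-U2 libraries 1A and 1B gave 16 (11 and 5), with fewer samples, and 1 surrogate variable gave 7 (5 and 2), where the cause was not tested. The share called higher was 45.3%, against 42.7% to 47.8% under other scaling, tests against no change and filters, and 31.3% in the authors' deposited table. With the replicate number as a block, 13 genes were called (3 and 10) over 4 blocks and 9 (4 and 5) with 1A and 1B in 1 block. Libraries of the same full name did not deviate together, with correlations of -0.22 to -0.08, and none correlated best with its namesake. With 1A and 1B taken as 1 number the result was mixed. ΔDMR1-U2 library 1A correlated best with wild-type library 1B, at 0.25, and ΔDMR1-U2 library 1B with wild-type library 3, at 0.145. The largest correlation across genotypes was 0.36, between ΔDMR1-U2 library 3 and wild-type library 1A. These libraries had cartilage and bone medians of -1.61 and -2.06, against -0.10 to 1.15 in the others. Their Col2a1 was at 11.1 and 28.1 CPM, against 263 to 1081 CPM in the others, so they shared a feature that crosses the genotypes. The numbers were not taken to pair animals, but pairing is not excluded. Of the 35 splits of the 8 libraries into 4 and 4, only the real one, 1 split, called as many genes. The highest other called 0, so the share of splits was under the 0.05 set in advance. The other splits mix the genotypes, so their counts do not show what libraries without any difference would give. A difference between the groups other than genotype, such as one of litter or dissection, would give the same result. Camera called 13 gene lists at a preset correlation, 0 with an estimated correlation and 0 with fry in its directional form, where 1 and 6 lists had an unadjusted p under 0.05; the mixed form of fry gave 10. Other settings, all at the preset correlation of 0.01, called 11 to 15 lists. The estimated correlations of the 13 called lists were higher, from 0.10 for immediate early to 0.82 for glucocorticoid-responsive genes. The range of 11 to 15 therefore does not show that the calls hold where genes move together. Of 2295 values of the 94 genes taken by the naming rule under alternatives, 1826 kept their direction and side of the threshold, 429 lost their call with the same direction, 9 gained one and 31 had the opposite sign, all of uncalled genes, with 0 past the threshold. Leaving out 1 library gave 19 of these, with ranges of -0.063 to 0.027 for Col3a1, -0.18 to 1.32 for Spp1, -0.027 to 0.18 for Car3, -0.078 to 0.051 for Des, -0.41 to 0.13 for Alas2, -0.24 to 0.026 for Trp63, -0.088 to 0.33 for Krt10, -0.092 to 0.072 for Hsp90aa1 and -0.055 to 0.063 for Tef. The others were Krt10 at -0.012 and Hsp90aa1 at 0.0058 with voom and sample weights, Cd81 at 0.025, Des at 0.072, Krt10 at -0.060 and Rn45s at 0.13 without both libraries 1A and 1B, and Cd81 at 0.019, Tssc4 at 0.013, Krt10 at -0.27, Hspb1 at -0.061, Hsp90aa1 at 0.16 and Rn45s at 0.072 with 1 surrogate variable. An alternative without mitochondrially encoded genes was not run because the table has none of them, those for normalized values or for statistics alone had nothing to apply to, and annotation terms were not tested because the table has no such column. Depth limits genes of low count such as Th, with 7 to 43 counts per library.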

Other observations

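The genes in the first paragraph, the test of a shift as large as that of Th and the limit on counts for genes of sympathetic cells were chosen after the values were seen; the other tests were set before their values were seen.

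Gli1, Ptch1 and Hhip, which are known targets of Hedgehog signalling, were called higher in ΔDMR1-U2 muscle. Gli1, a transcription factor, was at 21.2 ± 1.55 CPM against 14.6 ± 1.37 CPM (log2 fold change 0.54, adjusted p = 0.0301), Ptch1, the receptor, at 38.8 ± 4.46 against 26.7 ± 3.23 (0.54, adjusted p = 0.0457), and Hhip, a secreted inhibitor, at 26.2 ± 3.29 against 16.5 ± 3.07 (0.66, adjusted p = 0.0475, edgeR quasi-likelihood test, n = 4 each). Each was higher in all 4 ΔDMR1-U2 libraries than in any wild-type library. Such separation held in 171 of the 172 called genes, so it adds little to the calls. Gli2, Gli3 and Smo, components of the pathway, had 0.02, -0.04 and -0.03 and were not called. In the fits that left out 1 library, Gli1 kept its call without ΔDMR1-U2 library 1A, 1B or 2, Ptch1 without 1A or 2 and Hhip without 2 only, with log2 fold changes of 0.48 to 0.79 over the 3 genes. Among genes of myeloid cells, Cd209f fell by 2.15 on the log2 scale and Clec10a by 0.98, while Chi3l3 rose by 2.67, all at mean levels under 4 CPM. Cd209f was at 0.05 to 0.49 CPM in ΔDMR1-U2 libraries and Chi3l3 at 0.32 to 0.85 CPM in wild-type libraries, near the floor of the counts. Chi3l3 reached 6.30 CPM in ΔDMR1-U2 library 1B against 2.09 to 2.22 CPM in the others of its group. Without library 1B its log2 fold change was 2.11. Cd209f kept its call only without ΔDMR1-U2 library 1B or 2, Clec10a only without 1A or 2 and Chi3l3 only without 1A, 1B or 2, and the macrophage list was not called in the main comparison.

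Xist was near 0 in ΔDMR1-U2 library 1A, at 49 counts, although the label gives a female. A male is argued against by Y-linked genes, which had 3 counts, or 0.02562% of the counts of their X-linked partners. Full activity of both X chromosomes is argued against by 401 X-linked genes, whose median log2 ratio to the other 3 libraries was 0.0838 (bootstrap interval 0.06 to 0.11). That median was above those of all other libraries set against their own groups, at -0.08 to 0.05, so a partial rise is not excluded. A single X chromosome is a candidate explanation, as 4 genes that escape inactivation had a mean log2 ratio of -0.3988, with Kdm6a at -0.76, Kdm5c at -0.58, Eif2s3x at -0.46 and Ddx3x at 0.21. No biological explanation by genotype was tested, since the pattern is in 1 library of its group. Without X-linked genes 178 genes were called.

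Th was higher in ΔDMR1-U2, and Th is the only gene within 500 kb of Igf2as that edgeR called apart from Igf2as itself. More sympathetic nerve or adrenal tissue in the dissection cannot be told apart from a change in Th alone. The median log2 fold change of 6 other tested genes of such cells was 0.02082 (bootstrap interval -0.34 to 0.38), short of the 1 it would need. However, Dbh and Slc6a2 had under 20 counts per library on average. Ddc and Slc18a2, with averages of 716 and 252 in ΔDMR1-U2, would hide a small share. For that reason the call of Ddc as lower, at -0.48, decides nothing here (adjusted p = 0.0457, edgeR). Ddc kept that call only without ΔDMR1-U2 library 1A or 2. The remaining 2 genes, Gch1 at -0.16 and Hand2 at 0.41, were not called and are too few to decide. A shift of similar size around Igf2 is argued against by the 16 other tested genes within 500 kb, whose median absolute log2 fold change was 0.1497 (upper bootstrap bound 0.21). Whether they share a smaller shift cannot be told apart from the spread of other genes, as this median lay at percentile 62.37 of 10000 random lists matched on expression. An effect of the deletion on Th itself was not tested.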
